A study of Mus musculus with 20 samples.

How the data were processed

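Poly(A) RNA was sequenced from 20 mouse libraries, each named by the labels as a cell line. The lines are labelled as embryonic stem cells (ESCs) or as PGC-ESCs, after primordial germ cells (PGCs), in a series on the potency of PGCs placed in early embryos; the steps by which PGC-ESC lines were made are not given in the sources used here. The ESC groups were wildtype lines derived from host embryos (ESC Host, n = 4), lines without Bax derived earlier (ESC BaxKO, n = 2) and a Bax heterozygous line (ESC BaxHet, n = 1). The PGC-ESC groups carried either the Bax knockout (PGC-ESC BaxKO, n = 5) or a double knockout of Puma and Noxa, here called DKO (PGC-ESC DKO, n = 3). Epiblast-like cells (EpiLCs) were made from host lines 3 and 4 (EpiLC Host, n = 2) and from the DKO lines (EpiLC DKO, n = 3). The ESC protocol cultured cells with a GSK3 inhibitor, a MEK inhibitor and LIF. The Bax lines have a C57Bl6J/129SvEvRoEp strain label and the Host and DKO lines a C57Bl6J label, so Bax genotype, strain and time of derivation cannot be separated between these sets. Expression of an EGFP reporter also differs between the Bax lines and the Host lines. Within the C57Bl6J label, origin, DKO genotype and expression of an EGFP reporter differ together between PGC-ESC DKO and ESC Host. Comparisons of PGC-ESC with ESC lines that use these groups, alone or together with the Bax lines, therefore do not isolate origin.

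The authors deposited 1 table of read counts per gene, with 21361 genes and 20 libraries. All values were whole numbers, and no column belonged to another sample. The submitters' processing notes name STAR 2.7.7a and mouse build mm10; the counting tool and the gene annotation are not given in the sources used here. Library totals ran from 14255399 to 33376660 counts. Between replicates of a group, the chi-square per gene was 7.10 to 240.04 over 24 pairs, against an expectation near 1 for counting error alone, so spread between lines exceeded counting error. Fold floors and counting intervals given for genes with few counts cover counting error only. The p-values measure spread between these libraries, which the labels name as lines. The 13 mitochondrially encoded genes are absent from the table, so that list could not be tested.

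Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM scaling, the default filter on low counts and 1 coefficient for each of the 7 groups (13 residual degrees of freedom). The filter kept 16363 genes and left 4998 untested. All p-values of genes are two-sided and were adjusted by the Benjamini-Hochberg method over the 16363 genes, and a gene was called at an adjusted p under 0.05. Changes are log2 fold changes ± standard error with a prior count of 2 where log CPM is shown. The 11 comparisons were PGC-ESC against ESC within the Bax lines, the same within the C57Bl6J lines and averaged over both, 3 comparisons between the Bax lines and lines of the other strain label, both EpiLC groups against their parent lines, the EpiLC groups against each other, and the differences between the EpiLC responses and between the origin effects. A positive value means higher in the group named first. Levels in CPM, counts scaled by a library's total, are per library total for single genes by library or group (mean ± SD) and TMM-scaled where a pair of group means stands beside a fold change. In simulated data with 16363 genes and the libraries' own dispersions, of 200 changed genes the test recovered 37 to 68% at 2-fold and 83 to 96% at 4-fold in 6 of the comparisons, with 0.699 to 4.0% false calls among those made. The comparisons that cross the strain labels and the differences between effects were not simulated. Changed genes were drawn from those above a minimum mean level. Simulated counts were independent and held no structure between lines or Rn45s sets, so the share of false calls need not hold for the real libraries.

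Of 20 gene lists written from textbook knowledge, 19 had tested members: core pluripotency, naive pluripotency, formative and primed epiblast, FGF-ERK response, early germ cell, late germ cell, paternally expressed imprinted, maternally expressed imprinted, DNA methylation machinery, two-cell-like, primitive endoderm, trophoblast, mesendoderm, neuroectoderm, fibroblast and feeder, BCL-2 family, p53 targets, glycolysis and Y-linked genes. Lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with two-sided p-values adjusted over the lists of a comparison, and again with the correlation estimated. List counts are given over the adjustment for all genes and, where different, adjusted over the list alone. List scores, the mean log2 CPM of a list's members, were compared between 8 PGC-ESC and 7 ESC libraries by a two-sided exact permutation test over 6435 splits. Genes were named by a rule: the targeted genes, up to 4 called members of each list with the smallest adjusted p (otherwise the 2 most abundant), and up to 6 genes per direction with the largest fold, a mean of 5 CPM or more in the higher group and no overlap between libraries, without clone-style symbols, immunoglobulin and olfactory genes and pseudogenes. Genes named outside the rule (the Gm14 zinc fingers, AA467197, Acsm4, Bco1, Traip, Dusp9, Rn45s) were chosen after their values were seen. Lists, comparisons and tests, the naming rule and the alternatives of the next paragraph, except those it names as later, were fixed before the data were examined. Gene positions were taken from the RefSeq annotation of GRCm38.p6 by symbol, which placed 16276 of the tested genes.

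Alternatives were RLE scaling, DESeq2 1.42.0 (Wald test, Benjamini-Hochberg adjustment), no filter on low counts, a fit with only the groups compared, a block for the replicate number, a block for the line in the 10 ESC, PGC-ESC and EpiLC libraries of 5 lines, the expression of 4 Y-linked genes as a covariate, each library left out in turn, and for lists an estimated correlation, the fry test, median scores and scores without the BaxHet line. Settings chosen after the data had been seen were a term for 2 sets of libraries defined by Rn45s at 10000 CPM, that term with the Y-linked covariate, either set alone, no libraries of host line 4, a covariate for X-linked expression in 15 libraries, list scores permuted within strain label or Rn45s set, and fits of those 15 and of the 10 libraries with no covariate or block. The concentration of calls on any chromosome was compared with 10000 random draws of tested genes. A library left alone in its group was assumed to vary as the other groups do. Principal components used the 1000 most variable genes, and the X-linked shift used genes with a mean of 5 CPM or more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and counting intervals used SciPy 1.17.1. The BaxHet line, a single library, was kept in the fit and in figures but in no comparison of its own. Symbols of near-identical gene copies (Zscan4, Usp17l, Tdpoz and the Gm14 zinc fingers) may share reads, so their values are uncertain. Whether reads were shared between Eno1b and the enolase gene Eno1 was not checked, so the fold changes of Eno1b are uncertain as well.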

Results

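Bax, the pore-forming BCL-2 family protein of mitochondrial apoptosis (chromosome 7, 45461695 to 45466903), was at 2.05 ± 0.544 CPM (mean ± SD) in ESC BaxKO (n = 2) and 2.03 ± 0.211 CPM in PGC-ESC BaxKO (n = 5). It stood at 358 ± 118 CPM in ESC Host (n = 4), 392 ± 107 CPM in PGC-ESC DKO (n = 3) and 109.6 CPM in the BaxHet line. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, used for all genes, Bax fell relative to ESC Host in ESC BaxKO (log2 fold change -7.57 ± 0.43, adjusted p 8.33e-09) and in PGC-ESC BaxKO (-7.58 ± 0.28, adjusted p 1.08e-11). Pmaip1, the BH3-only gene that encodes Noxa (chromosome 18, 66458604 to 66465558), was at 2.99 ± 1.58 CPM in PGC-ESC DKO against 35.1 ± 17.2 CPM in ESC Host, a difference that did not pass (-3.52 ± 0.69, adjusted p 0.0567). After conversion to EpiLCs it was at 4.799 ± 0.916 CPM in the DKO lines (n = 3) against 324 ± 13.4 CPM in the Host lines (n = 2) and was lower (-6.06 ± 0.77, adjusted p 0.00118). Bbc3, the BH3-only gene that encodes Puma (chromosome 7, 16308398 to 16318334), was at 38.4 ± 10.8 CPM in PGC-ESC DKO and 43.5 ± 5.38 CPM in ESC Host (-0.12 ± 0.23, adjusted p 0.933). The labels give the DKO lines as Puma knockout, and whether the counted Bbc3 reads lie outside the deleted part is not given in the sources used here.

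EGFP, a reporter transcript present in the table, was at 8975 ± 657 CPM in PGC-ESC DKO, 3250 ± 207 CPM in PGC-ESC BaxKO and 3264 ± 238 CPM in ESC BaxKO. The BaxHet line had 1704 CPM, and ESC Host had 0 in 3 of 4 libraries and 0.547 CPM in Host 4. In EpiLCs EGFP was at 684 ± 120 CPM in the DKO lines and 0.147 ± 0.154 CPM in the Host lines. It fell between PGC-ESC DKO and EpiLC DKO (-3.92 ± 0.38, adjusted p 2.91e-07).

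**Figure D1:**
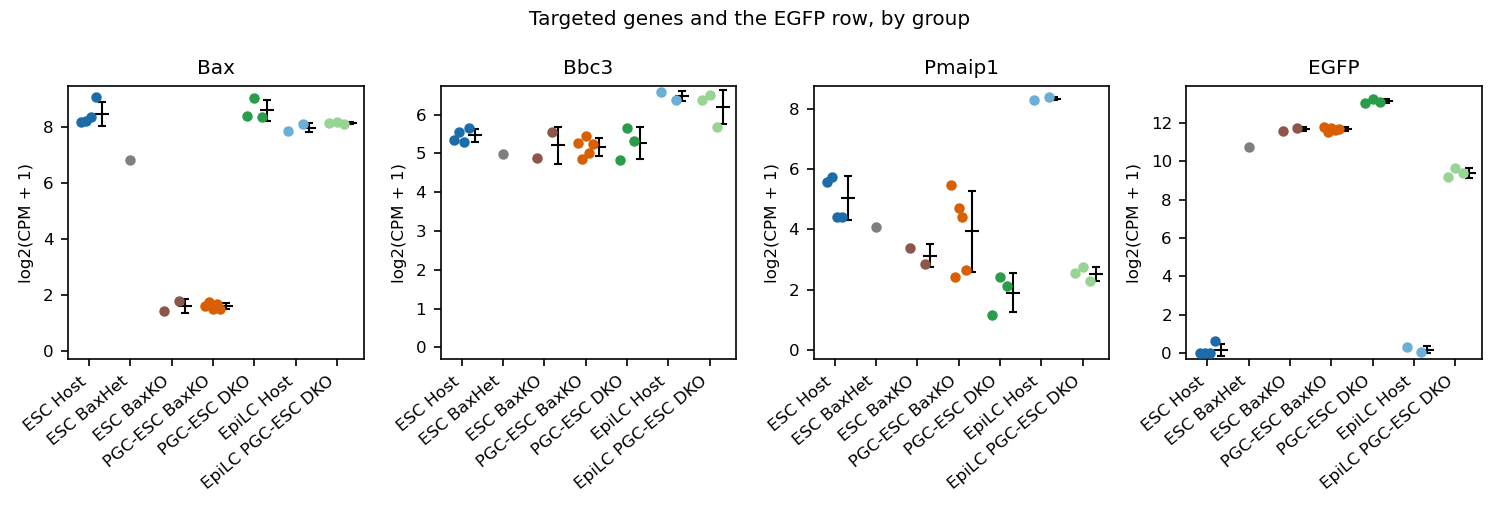
Bax, Bbc3, Pmaip1 and EGFP in the 7 groups, as log2 of CPM plus 1 on the vertical axis. Points are libraries and bars the group mean ± SD, with no SD for the single BaxHet library.

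In a principal component analysis of the 15 ESC and PGC-ESC libraries, the first component held 45.5% and the second 22.1% of the variance. Rn45s, the precursor of ribosomal RNA, was read at 1913 to 5106 CPM in 9 libraries (BaxHet, ESC BaxKO 1, ESC Host 1 and 2, and all PGC-ESC BaxKO) and at 17130.3 to 51924 CPM in the other 11. All PGC-ESC DKO and EpiLC libraries lay in the high set and all PGC-ESC BaxKO libraries in the low set. Y-linked genes averaged 61.1 and 47.0 CPM in ESC BaxKO 1 and 2, 53.5 and 52.998 CPM in PGC-ESC BaxKO 2 and 5, and 42.8 CPM in PGC-ESC DKO 3. They were at 3.84 CPM in ESC Host 4 and at 0 in all other ESC and PGC-ESC libraries. The median of 352 X-linked genes relative to 9787 autosomal genes, each gene centred over the libraries, was 0.77, 0.75 and 0.70 (log2) in PGC-ESC BaxKO 1, 3 and 4. It was -0.17 and -0.22 in PGC-ESC BaxKO 2 and 5 and at most 0.26, in the BaxHet line, elsewhere. The X-linked gene Dusp9, a phosphatase that removes phosphate from ERK, was at 224, 216 and 106 CPM in PGC-ESC BaxKO 1, 3 and 4 and at 13.3 and 16.1 CPM in 2 and 5. It was at 11.3 and 16.1 CPM in ESC BaxKO and 57.98 CPM in the BaxHet line. In the Host and DKO lines Dusp9 did not follow the Y-linked genes, with 112, 17.5, 71.98 and 62.7 CPM in ESC Host 1 to 4 and 39.9, 58.2 and 51.9 CPM in PGC-ESC DKO 1 to 3. Xist was at 0.587 to 10.9 CPM over all libraries.

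**Figure D2:**
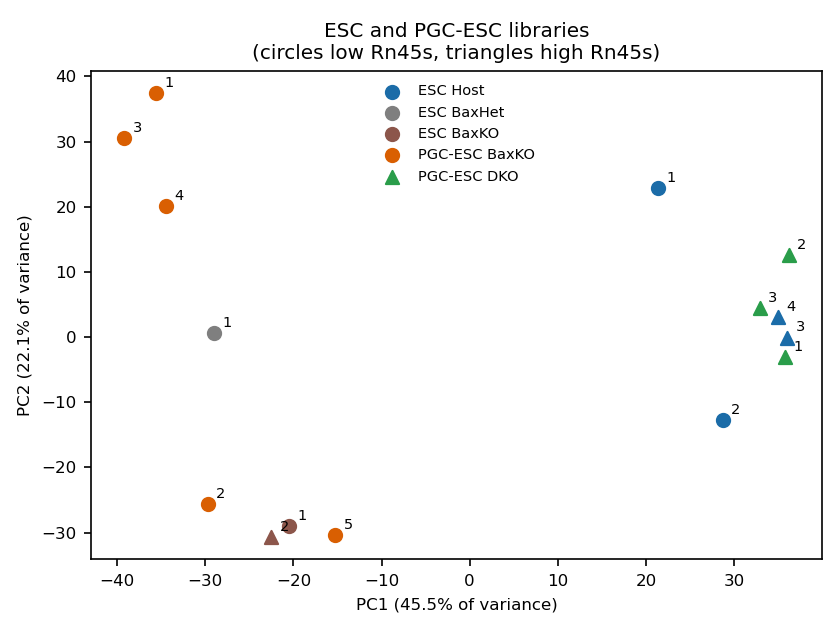
First (45.5%) and second (22.1%) principal components of the 15 ESC and PGC-ESC libraries, from log2 CPM of the 1000 most variable genes. Colours are groups, with circles for libraries of low and triangles for libraries of high Rn45s.

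**Figure D3:**
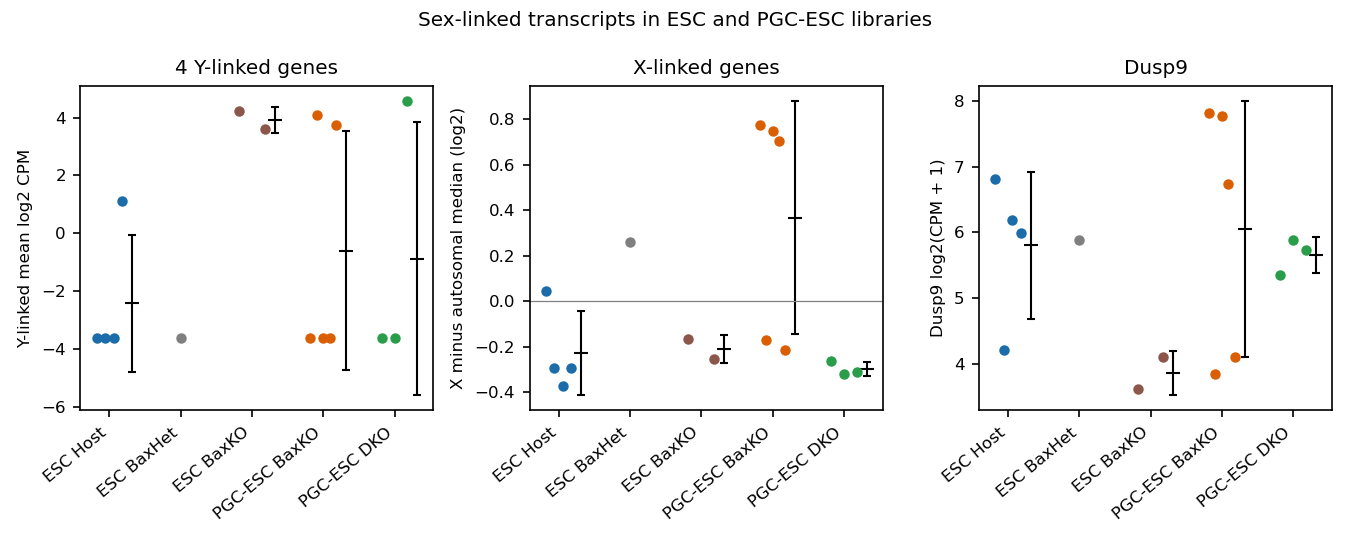
Mean log2 CPM of 4 Y-linked genes, the X-linked minus autosomal median (log2) and Dusp9 in the 5 ESC and PGC-ESC groups. Points are libraries.

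Within the Bax lines, PGC-ESC lines differed from ESC lines in 6 genes. Both ESC BaxKO lines expressed Y-linked genes, but of the PGC-ESC BaxKO lines only 2 and 5 did. Origin was therefore partly mixed with the division in Y-linked and X-linked expression. Wdfy1, an endosomal FYVE-domain protein (chromosome 1, 79702262 to 79776143), was higher in PGC-ESC BaxKO (54.1 against 25.7 CPM, log2 fold change 1.07 ± 0.17). Cdkn1c, a cyclin-dependent kinase inhibitor expressed from the maternal allele (chromosome 7, 143458339 to 143461059), was lower (1.93 against 9.42 CPM, -2.26 ± 0.37), as were the membrane glycoprotein gene Pdpn (-1.14 ± 0.18), the focal-adhesion gene Tes (-0.89 ± 0.15) and Acsm4 (-6.10 ± 1.02). Ubd, a ubiquitin-like modifier, had no counts in the 5 PGC-ESC BaxKO libraries and was at least 369.6-fold lower against a floor of 3 counts over the group, its reads in the ESC group coming from ESC BaxKO 1 alone. Each of the 6 had an adjusted p of 0.0487, while 1637 of 16363 genes had an unadjusted p under 0.05. For 55.6% of tested genes the 95% interval excluded a 2-fold change. Wdfy1 and Cdkn1c lost their calls without ESC BaxKO 1, ESC BaxKO 2 or PGC-ESC BaxKO 1, 3 or 4 (adjusted p 0.118 to 0.457 and 0.118 to 0.276), and Pdpn and Tes also without PGC-ESC BaxKO 5 (0.0541 to 0.421 and 0.0575 to 0.328). Acsm4 (0.0541 to 0.96) and Ubd (0.0521 to 1) lost theirs without ESC BaxKO 1 or any of the 5 PGC-ESC BaxKO libraries. In all, 1 gene was called without ESC BaxKO 1, 0 without PGC-ESC BaxKO 1, 3 or 4, and 12 without PGC-ESC BaxKO 2. With RLE scaling, with only the compared groups in the fit, with a Y-linked covariate, or in the 15 ESC and PGC-ESC libraries with or without an X-linked covariate edgeR called 0 genes, and DESeq2 called 70.

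Cdkn1c was the only member of the 19 lists called between PGC-ESC BaxKO and ESC BaxKO, and adjusted over the list alone 3 maternally expressed imprinted genes were lower. The core pluripotency list had a median of -0.01, with Pou5f1 at 0.05 ± 0.21 and Sox2 at 0.11 ± 0.16, and of the naive genes Tfcp2l1 was at 0.12 ± 0.19 and Dppa5a at -0.01 ± 0.25. Among the other lists, Alpl (early germ cell) was at -0.15 ± 0.12, Tdrd12 (late germ cell) at 0.27 ± 0.17, Uhrf1 (DNA methylation) at -0.03 ± 0.14, Ccng1 (p53 targets) at 0.00 ± 0.18 and Bak1 (BCL-2 family) at 0.36 ± 0.19. Adjusted over the list alone, 1 core pluripotency gene was higher, and 1 DNA methylation and 1 neuroectoderm gene were lower. Camera called the late germ cell list higher (median 0.55, adjusted p 0.0131) and the maternally expressed imprinted (median -0.25, adjusted p 0.0135), glycolysis (-0.21, adjusted p 0.0498) and Y-linked lists (-1.18, adjusted p 0.00488) lower. None of these calls held: the late germ cell list had an adjusted p of 0.757 with an estimated correlation, the maternally expressed list 0.471, glycolysis 0.831 and the Y-linked list 0.732. Late germ cell scores were 2.83, 2.54 and 2.21 in PGC-ESC BaxKO 1, 3 and 4, which lack Y-linked reads. They were 1.73 and 1.77 in lines 2 and 5, and 1.91 and 1.48 in ESC BaxKO 1 and 2. Maternally expressed imprinted scores were 2.67, 2.38 and 2.48 in lines 1, 3 and 4 and 2.94 and 2.87 in 2 and 5. In ESC BaxKO 1 and 2 they were 3.11 and 3.30.

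Within the C57Bl6J lines, 19 genes differed between PGC-ESC DKO and ESC Host, 9 higher and 10 lower. The groups differ in DKO genotype and the EGFP reporter as well as in origin. Besides EGFP (16.32 ± 0.58, adjusted p 7.16e-12), the higher genes were Pla2g4e, a phospholipase (chromosome 2, 120166412 to 120245630; 19.05 against 0.215 CPM, 6.39 ± 0.64, adjusted p 3.27e-05), and the cadherin gene Cdh6 (4.42 ± 0.55, adjusted p 0.000435). Ccbe1, a secreted protein of lymphatic growth (chromosome 18, 66056855 to 66291838; 3.81 ± 0.36, adjusted p 2.07e-05), Bco1 (4.28 ± 0.62, adjusted p 0.00321), Traip (1.31 ± 0.17, adjusted p 0.000558) and Wdfy1 (31.7 against 12.96 CPM, 1.29 ± 0.15, adjusted p 0.000184) were higher as well. Spic, an ETS-family transcription factor and the only list member called (naive pluripotency), fell (1.23 against 19.5 CPM, -4.03 ± 0.38, adjusted p 6.42e-05). Also lower were the zinc transporter gene Slc30a4 (-2.68 ± 0.29, adjusted p 6.42e-05), Spata5l1 (-1.53 ± 0.22, adjusted p 0.0026) and the zinc finger genes Gm14305 (-6.40 ± 0.67, adjusted p 5.85e-05) and Gm14410 (-2.31 ± 0.25, adjusted p 6.42e-05). AA467197 (adjusted p 2.48e-06) had 2 counts in the 3 DKO libraries and 1183 in the Host libraries, a ratio of 362.8-fold with a counting interval of 100.2 to 2999. Gm14295 had no counts in the DKO libraries and was at least 62.9-fold lower against the same floor.

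The formin gene Fmn2 (1.75 ± 0.33, adjusted p 0.0385) and the ciliary gene Pkhd1 (1.66 ± 0.31, adjusted p 0.0385) were also higher in PGC-ESC DKO. Lower were the protease inhibitor gene Serpina3m (-3.22 ± 0.59, adjusted p 0.034), Gm14393 (-1.81 ± 0.32, adjusted p 0.0239) and Zfp277 (-0.75 ± 0.12, adjusted p 0.0064). These 5 calls each depended on single libraries. Fmn2 was lost without ESC Host 1, 3 or 4 or DKO 1 or 3 (adjusted p 0.0594 to 0.272), Pkhd1 without ESC Host 2, 3 or 4 or any DKO library (0.0553 to 0.193). The call of Serpina3m was lost without ESC Host 1 or 3 or DKO 1 or 3 (0.0707 to 0.239), that of Gm14393 without ESC Host 1 or 2 or DKO 1 or 3 (0.0568 to 0.179) and that of Zfp277 without DKO 1 (0.0827) or DKO 3 (0.0643). Leaving out ESC Host 4 raised the count from 19 to 44, DESeq2 called 77, and a fit of the compared groups alone called 9. An unadjusted p under 0.05 was reached by 1195 genes, and for 59.9% of genes the 95% interval excluded a 2-fold change.

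Apart from Spic, no list member passed between PGC-ESC DKO and ESC Host. Pou5f1 was at 0.23 ± 0.19, Sox2 at 0.19 ± 0.15, Dnmt3b at 0.20 ± 0.26, Alpl at 0.15 ± 0.11, Trim28 at 0.03 ± 0.15 and Cdkn1a at 0.26 ± 0.19. Adjusted over the list alone, 2 two-cell-like genes were higher and 1 late germ cell, 1 naive and 1 BCL-2 family gene lower. Camera called the two-cell-like list higher (median 1.32, adjusted p 1.28e-12, Zscan4c at 1.06 ± 0.58), with adjusted p = 0.693 with an estimated correlation. It also called the late germ cell list lower (median -0.62, adjusted p 0.0108) and the p53 targets higher (0.12, adjusted p 0.0437), with adjusted p = 0.693 and adjusted p = 0.912 with an estimated correlation.

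Averaged over both strain labels, 13 genes differed between PGC-ESC (n = 8) and ESC lines (n = 6), 4 higher and 9 lower. Wdfy1 rose (42.9 against 19.3 CPM, 1.18 ± 0.12, adjusted p 4.77e-05). It was the only gene called in the same direction within both the Bax and the C57Bl6J lines (expected by chance 0.00055, Fisher's exact p 0.00055), and 0 lower genes were shared. Over all tested genes, fold changes of the Bax and the C57Bl6J comparisons had a Pearson r of -0.082 and a Spearman rho of -0.058. At an adjusted p under 0.01 or with RLE scaling the Bax lines had 0 calls, so no overlap could be counted. Spic (-1.90 ± 0.24, adjusted p 0.00303), Gm14305 (-3.30 ± 0.40) and AA467197 (-4.31 ± 0.38) were lower and EGFP higher (8.15 ± 0.41). Cdkn1c (3.09 against 8.99 CPM, -1.64 ± 0.27, adjusted p 0.0138) lost its call without ESC BaxKO 1 or 2 or PGC-ESC DKO 1 or 2 (0.0566 to 0.0864), and Slc30a4 (-1.21 ± 0.19, adjusted p 0.0112) without the same libraries (0.0589 to 0.08). Pla2g4e (3.10 ± 0.45) and Ccbe1 (1.72 ± 0.26) lost theirs without ESC BaxKO 1 (0.0645 and 0.0871) or ESC BaxKO 2 (0.119 and 0.121). Apart from Wdfy1 and Cdkn1c, the averages of the genes named here come from the C57Bl6J lines. Within the Bax lines EGFP was at -0.03, Spic at 0.23, Gm14305 at -0.19, AA467197 at -0.40, Slc30a4 at 0.26, Pla2g4e at -0.19 and Ccbe1 at -0.37, none of them called, and each differed in origin effect between the labels. The count was 6 without ESC BaxKO 1, 23 without PGC-ESC BaxKO 2 and 21 without PGC-ESC BaxKO 5, and DESeq2 called 58. At an unadjusted p under 0.05 there were 1233 genes, and the 95% interval excluded a 2-fold change for 69.9%.

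Across the lists, this comparison called Spic among the naive genes and Cdkn1c among the maternally expressed imprinted genes, of which 5 were lower adjusted over the list alone. Adjusted over the list alone, 1 late germ cell and 1 BCL-2 family gene were also lower. Camera called the paternally expressed imprinted list higher (median 0.25, adjusted p 0.0439) and the two-cell-like list higher (0.88, adjusted p 7.29e-05), but with an estimated correlation the values were adjusted p = 0.938 and adjusted p = 0.968. The maternally expressed imprinted (median -0.13, adjusted p 0.0409) and glycolysis lists (-0.12, adjusted p 0.0409) were lower, with adjusted p = 0.682 and adjusted p = 0.968 with an estimated correlation. For the Y-linked list the median (1.51) and mean (1.53) were positive while camera's direction was down, without a call (adjusted p 0.738). Mean scores gave no list past the adjusted exact permutation test between 8 PGC-ESC and 7 ESC libraries. The maternally expressed imprinted score was 2.75 ± 0.231 against 3.07 ± 0.226 (difference -0.32, exact permutation p 0.0194, adjusted p 0.369), core pluripotency differed by -0.05 (exact permutation p 0.593) and naive pluripotency by -0.02 (exact permutation p 0.833). That test permutes over strain label and Rn45s set together. Permuted within strain label or within Rn45s set, settings chosen after the values were seen, again 0 lists passed, with a maternally expressed imprinted difference of -0.30 (exact permutation p 0.0332, adjusted p 0.6301) and -0.28 (exact permutation p 0.0302, adjusted p 0.573). Some lists changed direction between the low (n = 5 and 4) and high sets (n = 3 and 3, smallest possible p 0.1). The two-cell-like difference was -0.58 (exact permutation p 0.532) and 1.96 (exact permutation p 0.1), and that of primitive endoderm -0.34 (exact permutation p 0.111) and 0.30 (exact permutation p 0.1). The PGC-ESC libraries were all BaxKO in the low set and all DKO in the high set, while both ESC sides mixed Bax and Host lines. Strain label and genotype therefore changed with the set, and the change of direction cannot be assigned to any of them.

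**Figure D4:**
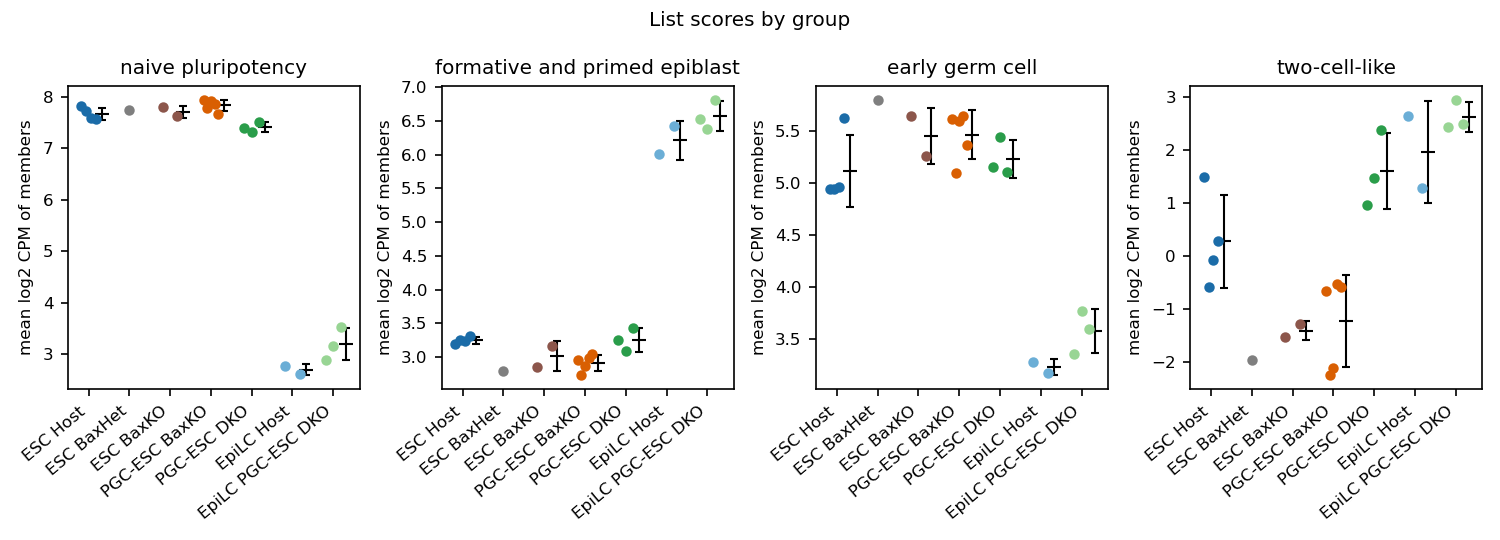
Scores of the naive, formative, early germ cell and two-cell-like lists, as mean log2 CPM of the members on the vertical axis, in the 7 groups. Points are libraries and bars the group mean ± SD.

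The origin effect differed between the Bax and the C57Bl6J lines in 13 genes, 8 higher and 5 lower in the Bax lines. In the C57Bl6J lines this effect includes the DKO genotype and the EGFP reporter, so these differences cannot be assigned to origin. Serpina3m (4.91 ± 0.87), Spic (4.26 ± 0.52, adjusted p 0.00209), Slc30a4 (2.94 ± 0.41) and Zfp277 (1.03 ± 0.17) had positive and Pla2g4e (-6.58 ± 0.79), Ccbe1 (-4.17 ± 0.49), Traip (-1.40 ± 0.25) and Tes (-1.15 ± 0.21, adjusted p 0.0486) negative differences. The rest were EGFP (-16.34), AA467197 (7.82), Gm14295 (9.61), Gm14305 (6.21) and Gm14410 (2.38), where fitted values of Gm14295 are no bound since it is at 0 in the DKO lines. Slc30a4 was lost without ESC BaxKO 1 (adjusted p 0.0502), Gm14410 without ESC BaxKO 1 (0.0752) or 2 (0.0831). Zfp277 (0.0506 to 0.301), Traip (0.0518 to 0.186), Serpina3m (0.0621 to 0.389) and Tes (0.0553 to 0.23) were each lost without any of 5, 9, 9 and 12 libraries. Of the lists, naive pluripotency had 1 called member (Spic), and late germ cell had 2 higher adjusted over the list alone. Camera called late germ cell higher (median 1.06, adjusted p 0.00021), two-cell-like lower (-0.77, adjusted p 0.0113) and Y-linked lower (-5.39, adjusted p 0.0482), with adjusted p = 0.585, adjusted p = 0.768 and adjusted p = 0.585 with an estimated correlation. A Rn45s set term left 7 genes called, and DESeq2 called 52.

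PGC-ESC BaxKO differed from ESC Host in 2834 genes, 1300 higher and 1534 lower, with strain label, Bax genotype, derivation and the EGFP reporter differing together. Rn45s set and X-linked expression differed between these groups in part. Zfp42, a zinc finger gene of naive pluripotency (chromosome 8, 43295067 to 43307009), rose (447 against 147 CPM, 1.61 ± 0.08, adjusted p 9.93e-10). The largest increases under the naming rule, besides EGFP, were Pla2g4e (6.01 ± 0.61, adjusted p 7.39e-06), the enolase gene Eno1b (291 against 4.68 CPM, 5.93 ± 0.45, adjusted p 2.44e-07), Kbtbd11 (5.63 ± 0.55), Ushbp1 (5.46 ± 0.55) and Pkd2l1 (4.76 ± 0.78). Wdfy1 rose as well (2.06 ± 0.14, adjusted p 6.96e-08). Ubd was at 0 in PGC-ESC BaxKO and at least 927.6-fold lower against the floor, and the serum amyloid gene Saa3 (-7.92 ± 0.60, adjusted p 2.44e-07), the calpain gene Capn11 (-5.56 ± 0.55) and the fucosyltransferase gene Fut2 (-4.55 ± 0.65, adjusted p 0.000236) fell.

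The called members printed here are among those that kept their calls in PGC-ESC BaxKO against ESC Host without each library in turn. Of 70 called genes named for it, 12 lost the call without PGC-ESC BaxKO 4 and 2 to 10 without each other library. In the low Rn45s set alone 42 lost it, and with the X-linked covariate 37 (11 in the same 15 libraries without it). Of the core pluripotency list 3 of 15 fell (adjusted over the list alone 1 rose and 4 fell), among them Dppa4 (-0.62 ± 0.11) and Tdgf1 (-0.75 ± 0.16), and 2 of 20 naive genes rose. In the formative list 2 rose and 6 of 19 fell, with Tead2 (-1.27 ± 0.21) and Sox11 (-1.60 ± 0.37) lower and Grhl2 (1.89 ± 0.40) higher. In the FGF-ERK response list 2 rose and 3 fell (5 adjusted over the list alone), with Ccnd1 (0.88 ± 0.19) up and Spry2 (-0.88 ± 0.18) down. Early germ cell genes rose in 4 cases and fell in 0, Kit (323 against 191 CPM, 0.76 ± 0.17) and Itgb3 (1.67 ± 0.43) among them. Late germ cell genes rose in 4 and fell in 2, with Tdrd12 (0.91 ± 0.13) and Ddx4 (-1.44 ± 0.30). Of the paternally expressed imprinted genes 3 rose and 1 fell, with Inpp5f (1.24 ± 0.18) and Igf2 (-3.49 ± 0.61), and of the maternally expressed 1 rose and 3 fell, with Cdkn1c (-2.12 ± 0.33) and Ascl2 (-1.86 ± 0.43). Dnmt3l (16.5 against 87.3 CPM, -2.40 ± 0.51) and Zfp57 (-0.71 ± 0.17) were among 3 DNA methylation genes that fell, while 1 rose.

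Among markers of other cell types, Sparc (381 against 759 CPM, -0.996 ± 0.17) and Lama1 (1.72 ± 0.33) represent 4 primitive endoderm genes lower (5 adjusted over the list alone) and 1 higher in PGC-ESC BaxKO than in ESC Host. Eomes (-1.63 ± 0.26) and Tfap2a (1.70 ± 0.39) represent 4 trophoblast genes lower and 3 higher. Mesendoderm had 2 higher (3 adjusted over the list alone) and 1 lower, with Lefty2 (1.44 ± 0.36) and Nodal (-0.58 ± 0.12), neuroectoderm 1 higher (Nes, 0.80 ± 0.19) and the fibroblast and feeder list 1 lower. Bmf (-1.07 ± 0.23) and Bcl2l1 (-0.40 ± 0.09) fell in the BCL-2 family, and 1 p53 target rose (the X-linked gene Eda2r, 2.04 ± 0.43) while 3 fell. In glycolysis 1 rose and 1 fell (Pfkm, -0.66 ± 0.16; adjusted over the list alone 0 rose), and no Y-linked gene passed (Ddx3y 4.84 ± 2.51, adjusted p 0.181). The two-cell-like list had 11 of 19 lower (15 adjusted over the list alone) with Sp110 at -2.13 ± 0.46, and was the only list camera called (median -1.92, adjusted p 0.000152), with adjusted p = 0.908 with an estimated correlation. The count of 2834 genes fell to 1768 without PGC-ESC BaxKO 4, 1862 without ESC Host 3 and 1845 without ESC Host 4. It was 1024 with the compared groups alone, 1108 with the Rn45s term, 361 in the low Rn45s set alone and 981 with the X-linked covariate (1917 in the same 15 libraries without it).

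ESC BaxKO differed from ESC Host in 821 genes, 451 higher and 370 lower. Zfp42 rose (442 against 147 CPM, 1.59 ± 0.10, adjusted p 2.15e-08), as did Pla2g4e (6.20 ± 0.65, adjusted p 3.31e-05), Eno1b (334 against 4.68 CPM, 6.13 ± 0.48, adjusted p 6.91e-07), the interferon-inducible gene Slfn8 (5.78 ± 0.65), Kbtbd11 (5.64 ± 0.58) and Ushbp1 (5.37 ± 0.59). Saa3 had 3 counts in ESC BaxKO and was lower by a ratio of 140.4-fold with a counting interval of 47.9 to 682 (adjusted p 8.94e-05). Ccnd1 (309 against 118 CPM, 1.39 ± 0.23, adjusted p 0.00224) and Inpp5f (1.32 ± 0.22, adjusted p 0.00244) rose. Each of these kept its call without any single library. Of 38 called genes named for ESC BaxKO against ESC Host, only 6 kept the call in the low Rn45s set alone, 14 with the compared groups alone and 18 with the Y-linked covariate. The neural transcription factor genes Olig2 (0.222 against 85.6 CPM, -8.67 ± 2.19, adjusted p 0.0307) and Olig1 (-8.03 ± 1.85, adjusted p 0.0191) were lower, and both calls were lost without ESC BaxKO 1 (0.222 and 0.181) or ESC BaxKO 2 (0.217 and 0.168). Laminin Lama1 (2.10 ± 0.40, adjusted p 0.00566) and Tfap2a (2.63 ± 0.46, adjusted p 0.00344) rose but not without ESC BaxKO 2 (0.0922 and 0.0658). The count was 245 without ESC BaxKO 1, 182 without ESC BaxKO 2 and 537 without ESC Host 3, and it was 406 with a block for the replicate number, 314 with the Y-linked covariate, 136 with the compared groups alone and 1416 by DESeq2. In the 15 ESC and PGC-ESC libraries it was 399 and, with the X-linked covariate, 925.

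By list, ESC BaxKO against ESC Host gave 3 core pluripotency genes lower, 1 naive gene higher, 2 formative genes lower (5 adjusted over the list alone) and 1 FGF-ERK response gene in each direction. Early germ cell had 1 higher (4 adjusted over the list alone), late germ cell 1 higher (with 3 lower adjusted over the list alone), paternally expressed imprinted 1 higher and 1 lower (3 adjusted over the list alone) and maternally expressed imprinted 1 higher. Primitive endoderm had 1 in each direction, trophoblast 1 higher and 2 lower (3 and 2 adjusted over the list alone), mesendoderm 1 higher (with 1 lower adjusted over the list alone), neuroectoderm 2 higher (3 adjusted over the list alone) and 1 lower, and the fibroblast list and the BCL-2 family 1 higher each. None passed among DNA methylation (Trim28 0.14 ± 0.17; 1 lower adjusted over the list alone), p53 (Cdkn1a 0.08 ± 0.21), glycolysis (Gapdh -0.10 ± 0.19) and Y-linked genes (Ddx3y 6.08 ± 2.79, adjusted p 0.225). The two-cell-like list had 3 lower (15 adjusted over the list alone) and a median of -2.47, or -2.39 with a member at 0 set to its bound (camera adjusted p 0.000169), with adjusted p = 0.821 with an estimated correlation. Camera also called the Y-linked list higher (median 5.63, adjusted p 0.0436), with adjusted p = 0.821 with an estimated correlation.

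Between the PGC-ESC groups, 3858 genes differed, 1989 higher and 1869 lower in PGC-ESC BaxKO than in PGC-ESC DKO, with genotype, strain label and Rn45s set differing together. Zfp42 (447 against 153 CPM, 1.55 ± 0.09, adjusted p 1.65e-08), Spic (28.3 against 1.23 CPM, 4.57 ± 0.38, adjusted p 4.55e-06) and Eno1b (291 against 2.85 CPM, 6.61 ± 0.54, adjusted p 8.03e-07) were higher. So were Kbtbd11 (7.38 ± 0.74), the methyltransferase gene Bhmt (6.71 ± 0.79), Ushbp1 (6.02 ± 0.68) and Crxos (5.86 ± 0.58). Bax (-7.76 ± 0.28, adjusted p 1.16e-11), Saa3 (-8.32 ± 0.61, adjusted p 2.4e-07), Capn11 (-5.77 ± 0.57) and Cdh6 (-5.28 ± 0.54) were lower, Ubd was at least 1410.2-fold lower, and EGFP was lower (-1.63 ± 0.30, adjusted p 0.00163). Pmaip1 was higher (2.60 ± 0.66, adjusted p 0.0107), a call lost without PGC-ESC DKO 1 (2.16, adjusted p 0.0506). Its level was 43.4, 25.3 and 20.1 CPM in PGC-ESC BaxKO 1, 3 and 4, but 4.34 and 5.36 CPM in lines 2 and 5, close to the 1.26, 4.35 and 3.35 CPM of the DKO lines, and its adjusted p ran from 0.000809 by DESeq2 to 0.722 with the X-linked covariate (0.0284 in the same 15 libraries without it). Without PGC-ESC DKO 2 the count was 1552. With the Rn45s term it was 204, and 973 with the X-linked covariate (2826 in the same 15 libraries without it).

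The list members printed for the PGC-ESC groups are among those that kept their calls without each library. Of 74 called genes named for this comparison, 25 lost the call without PGC-ESC DKO 3, 22 without DKO 2, 16 without PGC-ESC BaxKO 4, and 2 to 10 without each other library. With the Rn45s term 55 lost it, and with the X-linked covariate 44 (8 in the same 15 libraries without it), where 1 more turned. Core pluripotency had 3 lower, with Dppa4 (-0.56 ± 0.12) and Utf1 (-1.80 ± 0.40), and naive pluripotency 4 higher (3 adjusted over the list alone). Wnt8a (-1.75 ± 0.36) and Tead2 (-1.10 ± 0.23) were among 5 formative genes lower (6 adjusted over the list alone), with 3 higher. FGF-ERK response had 1 higher and 3 lower (2 and 3 adjusted over the list alone), early germ cell 2 higher and 2 lower with Kit at 0.99 ± 0.19. Late germ cell had 5 higher and 0 lower with Sycp1 (2.54 ± 0.44), Stk31 (1.76 ± 0.32) and Piwil2 (1.68 ± 0.39). Igf2r (169 against 59.5 CPM, 1.51 ± 0.33) was among 2 maternally expressed imprinted genes higher, with 2 lower, and Inpp5f (1.46 ± 0.21) was the 1 paternally expressed gene higher against 5 lower. DNA methylation had 1 higher and 2 lower, primitive endoderm 1 and 1, trophoblast 1 and 4 (3 and 4 adjusted over the list alone) with Eomes at -1.93 ± 0.27. Mesendoderm had 1 and 2 (1 and 1 adjusted over the list alone), neuroectoderm 1 and 1 with Sox1 at -1.10 ± 0.26, and the fibroblast list 1 and 1.

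The BCL-2 family had 1 higher and 1 lower (Bcl2l1, an anti-apoptotic member, 51.7 against 83.2 CPM, -0.68 ± 0.10, adjusted p 0.000386) in PGC-ESC BaxKO against PGC-ESC DKO. In the p53 list 4 genes were lower (5 adjusted over the list alone), with Plk2 at -1.61 ± 0.30, and in glycolysis 3 were higher, with the glucose transporter gene Slc2a1 (0.79 ± 0.17), and 1 lower (Pfkm, -0.76 ± 0.17). No Y-linked gene passed. The two-cell-like list had 16 of 19 lower, Sp110 (-3.10 ± 0.48) and Tcstv1 (-4.10 ± 0.57) among them, and a median of -3.05 (camera adjusted p 1.59e-11), with adjusted p = 0.821 with an estimated correlation.

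Conversion of Host lines to EpiLCs changed 7206 genes (3663 higher and 3543 lower in EpiLC Host than in ESC Host). Esrrb, a nuclear receptor of naive pluripotency (chromosome 12, 86361117 to 86521628), fell from 840.02 to 30.8 CPM (-4.77 ± 0.21, adjusted p 5.51e-11), and 19 of 20 naive genes fell, with Tfcp2l1 (-7.13 ± 0.28) and Zfp42 (-2.61 ± 0.12). Of 19 formative and primed epiblast genes 16 rose and 1 fell, with Fgf5 (chromosome 5, 98254184 to 98277033) at 54.6 against 0.339 CPM (7.38 ± 0.48, adjusted p 3.4e-09) and Pou3f1 at 329 against 6.31 CPM (5.71 ± 0.33). The naive (median -4.59, camera adjusted p 4.83e-17), formative (2.98, adjusted p 3.27e-09) and early germ cell lists (-2.47, adjusted p 3.13e-05) were called with the preset and with an estimated correlation (adjusted p 0.00221, 0.00499 and 0.0176). Early germ cell genes fell in 11 cases and rose in 0, with Alpl (-2.62 ± 0.14) and Kit (-3.28 ± 0.26). Prdm14 (chromosome 1, 13113428 to 13127163) had 2 counts in EpiLC Host, a ratio of 1786.5-fold lower with a counting interval of 494.4 to 14754. The carbonic anhydrase gene Car4 (chromosome 11, 84957754 to 84966054; 106 against 0.134 CPM, 9.50 ± 0.52) and Fndc3c1 (8.66 ± 0.38) rose most among genes of the naming rule with over 3 counts in both groups. The cation channel gene Trpm1 (chromosome 7, 64153835 to 64269772) and the cytokine gene Osm had no counts in EpiLC Host and were at least 1457.7-fold and 343.4-fold lower.

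Within the other lists, core pluripotency genes rose in 5 and fell in 6 cases in EpiLC Host, with Sox2 (101 against 763 CPM, -2.92 ± 0.20) and Pou5f1 (-1.21 ± 0.23) lower and Utf1 (2.31 ± 0.46) higher. FGF-ERK response genes rose in 7 cases (10 adjusted over the list alone) and fell in 1, with Dusp6 at 267 against 8.14 CPM (5.03 ± 0.32) and Spry4 at 3.88 ± 0.57 (median 1.15, camera adjusted p 0.00325), with adjusted p = 0.188 with an estimated correlation. Late germ cell genes rose in 10 and fell in 5 (Tdrd12, -2.52 ± 0.20), and paternally expressed imprinted genes rose in 12 and fell in 5 (Nnat, 3.82 ± 0.34). Maternally expressed imprinted genes rose in 10 and fell in 2 (3 adjusted over the list alone), with Cdkn1c at 86.1 against 8.56 CPM (3.34 ± 0.38; median 1.13, camera adjusted p 0.0224), with adjusted p = 0.188 with an estimated correlation. The de novo methyltransferase genes Dnmt3b (1044 against 139.9 CPM, 2.90 ± 0.28) and Dnmt3a (429 against 74.7 CPM, 2.52 ± 0.35) rose among 5 DNA methylation genes, while 6 fell, Zfp57 (-3.14 ± 0.27) and Tet2 (-3.21 ± 0.46) among them.

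Primitive endoderm genes rose in 4 (6 adjusted over the list alone) and fell in 4 in EpiLC Host, and trophoblast genes in 2 and 5. Mesendoderm genes rose in 5 and fell in 3 (Lefty1, 775 against 19.9 CPM, 5.29 ± 0.53; Sp5, -6.47 ± 0.51) and neuroectoderm in 5 and 2 (Sox1, 91.8 against 2.65 CPM, 5.10 ± 0.29). The fibroblast and feeder list had 7 higher (Tagln, 5.51 ± 0.35) and 0 lower, or 1 lower adjusted over the list alone (median 2.47, camera adjusted p 0.00291), with adjusted p = 0.305 with an estimated correlation. Two-cell-like genes rose in 9 cases (11 adjusted over the list alone; median 1.65, camera adjusted p 0.00596), with adjusted p = 0.655 with an estimated correlation. Zscan4d (2.65 ± 0.67, adjusted p 0.0037) and Zscan4f (2.67 ± 0.64, adjusted p 0.00263) were not called without EpiLC Host 3 (0.152 and 0.11). In the BCL-2 family 7 rose and 4 fell, with the BH3-only gene Bcl2l11 (48.9 against 13.8 CPM, 1.82 ± 0.17) and Bcl2 (4.83 ± 0.44) higher and Bcl2l1 (-0.67 ± 0.13) lower. The p53 list had 2 higher and 4 lower (Cdkn1a, -1.005 ± 0.22) and glycolysis 4 higher and 3 lower (Pfkp, -3.31 ± 0.34), and no Y-linked gene passed. Pmaip1 (3.10 ± 0.61, adjusted p 0.000542) and Bbc3 (0.87 ± 0.26, adjusted p 0.0104) rose and Bax was at -0.70 ± 0.28 (adjusted p 0.0508).

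Conversion of the DKO lines changed 7792 genes (4105 higher and 3687 lower in EpiLC DKO than in PGC-ESC DKO). Esrrb fell from 859 to 41.1 CPM (-4.39 ± 0.18, adjusted p 9.79e-12) with 19 of 20 naive genes (median -3.96, camera adjusted p 1.22e-17). Fgf5 (53.7 against 0.360 CPM, 7.17 ± 0.54) and Pou3f1 (432 against 5.80 CPM, 6.23 ± 0.37) rose with 16 of 19 formative genes (median 3.70, camera adjusted p 2.04e-09). The early germ cell list had 11 lower (12 adjusted over the list alone) and 0 higher, with Alpl at -2.61 ± 0.12 (median -2.19, camera adjusted p 1.85e-05). These calls also stood with an estimated correlation (adjusted p 0.00203, 0.00427 and 0.0161). Car4, Mal2 and Kynu had no counts in PGC-ESC DKO and were at least 1358.6-fold, 252-fold and 180.3-fold higher, while Srarp and the T-cell receptor component Cd3g had none in EpiLC DKO and were at least 409.6-fold and 153-fold lower. Trpm1 (-10.75 ± 0.51) and Osm (-8.55 ± 0.48) fell. Bbc3 rose (0.75 ± 0.25, adjusted p 0.0203), Pmaip1 was at 0.56 ± 0.70 (adjusted p 0.534), and Bax fell (-0.70 ± 0.26, adjusted p 0.0334) but not without EpiLC DKO 1, 2 or 3 or PGC-ESC DKO 2 (0.0713 to 0.225).

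Of the other lists in the DKO lines, core pluripotency had 5 higher (Lin28a, 2.53 ± 0.51) and 4 lower (Sox2, -2.62 ± 0.17), and late germ cell 13 and 5 (Tdrd1, 5.46 ± 0.65). Paternally expressed imprinted genes had 11 and 5 (Nnat, 3.75 ± 0.37) and DNA methylation 4 and 5, or 5 and 5 adjusted over the list alone, with Dnmt3a at 610.5 against 39.5 CPM (3.95 ± 0.39). FGF-ERK response had 10 higher and 1 lower, with Dusp4 (4.46 ± 0.32) and Dusp6 (4.72 ± 0.34; median 1.44, camera adjusted p 0.000666), with adjusted p = 0.128 with an estimated correlation. Maternally expressed imprinted genes rose in 12 and fell in 2 (14 and 3 adjusted over the list alone), with Cdkn1c at 2.62 ± 0.40 (median 1.55, camera adjusted p 0.0309), with adjusted p = 0.222 with an estimated correlation. Primitive endoderm had 6 higher and 4 lower, trophoblast 2 and 6 (7 lower adjusted over the list alone), mesendoderm 5 and 3, and neuroectoderm 5 and 2 (Sox1, 3.91 ± 0.30). In the same order the counts were 8 and 4 for the BCL-2 family (Bcl2l11, 1.97 ± 0.17), 2 and 5 for p53 targets, 8 and 2 for glycolysis (3 lower adjusted over the list alone; Slc2a1, 1.49 ± 0.18) and 0 and 0 for Y-linked genes. The fibroblast and feeder list had 6 higher (Tagln, 4.65 ± 0.38; median 1.79, camera adjusted p 0.0107), with adjusted p = 0.399 with an estimated correlation. The two-cell-like list had 5 higher, 0 adjusted over the list alone (median 1.01, camera adjusted p 0.0459), with adjusted p = 0.75 with an estimated correlation.

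Fold changes of the Host and the DKO conversions correlated over the 16363 genes (Pearson r 0.913, Spearman rho 0.912), where genes are not independent replicates. Both comparisons called 3244 genes higher (919 expected for independent lists) and 2989 lower (798 expected), and 1 gene in opposite directions. The comparisons share no library.

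**Figure D5:**
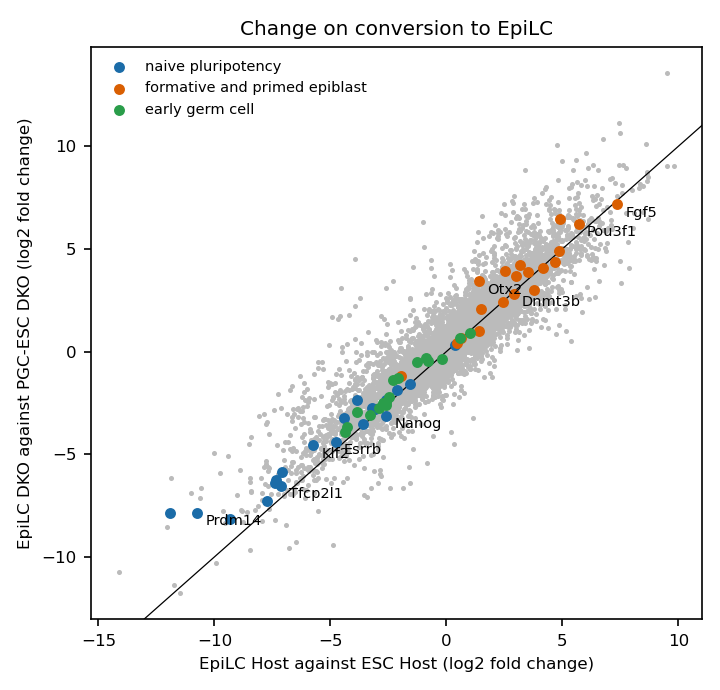
Log2 fold change of EpiLC Host against ESC Host (horizontal) and of EpiLC DKO against PGC-ESC DKO (vertical) for the tested genes. Members of the naive, formative and early germ cell lists are coloured, and the line marks equal change.

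EpiLC DKO differed from EpiLC Host in 7 genes. EGFP (12.20 ± 0.74, adjusted p 5.54e-08) and Wdfy1 (20.9 against 6.45 CPM, 1.69 ± 0.19, adjusted p 0.000455) were higher. Pmaip1 (-6.06 ± 0.77, adjusted p 0.00118) and Gm14305 (-5.999 ± 0.73, adjusted p 0.000713) were lower, and Gm14295 had no counts in EpiLC DKO, at least 93.8-fold lower. Gm14410 (-1.81 ± 0.27, adjusted p 0.00906) lost its call without EpiLC Host 3 or 4 or EpiLC DKO 2 or 3 (0.0668 to 0.137). Ivd, a dehydrogenase of leucine breakdown (24.7 against 43.7 CPM, -0.82 ± 0.14, adjusted p 0.0251), lost its call without any of the 5 libraries (0.0528 to 0.416). EGFP, Wdfy1, Gm14295, Gm14305 and Gm14410 were also called in the same directions between PGC-ESC DKO and ESC Host (2 higher and 3 lower). The EpiLCs were made from those DKO lines and from 2 of those Host lines, so the overlap is no independent repeat, and the 3 lower genes are zinc fingers that may share reads. The count was 11 without EpiLC DKO 1 and 12 with the Y-linked covariate, DESeq2 called 33, and 498 genes had an unadjusted p under 0.05.

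No list member was called between EpiLC DKO and EpiLC Host, with Tdgf1 at -0.34 ± 0.22, Nanog at -0.58 ± 0.32, Dnmt3b at 0.12 ± 0.31, Tdrd12 at 0.72 ± 0.19 (adjusted p 0.528) and Tagln at -1.35 ± 0.33 (adjusted p 0.444). Adjusted over the list alone, 2 naive and 1 late germ cell genes were higher, 1 maternally expressed imprinted gene was higher and 1 lower, and 2 fibroblast and feeder genes were lower. Camera called 7 lists higher, among them two-cell-like (median 0.47, adjusted p 3.2e-07), naive (0.44, adjusted p 9.89e-05), formative (0.12, adjusted p 0.000119) and paternally expressed imprinted (0.28, adjusted p 9.89e-05). With an estimated correlation these had adjusted p = 0.298, adjusted p = 0.119, adjusted p = 0.113 and adjusted p = 0.113. Core pluripotency (0.17, adjusted p 0.009), early germ cell (0.33, adjusted p 0.00908) and glycolysis (0.14, adjusted p 0.0222) had adjusted p = 0.24, adjusted p = 0.149 and adjusted p = 0.613 with an estimated correlation.

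The EpiLC response of the DKO lines differed from that of the Host lines in 1 gene. Ccbe1 fell in the DKO lines (-3.24 ± 0.39, adjusted p 3.23e-06) and rose in the Host lines (1.13 ± 0.40, adjusted p 0.0296), a difference of -4.37 ± 0.55 (adjusted p 0.00486). The difference lost its call without EpiLC Host 4 (-4.10, adjusted p 0.0979) and with the compared groups alone (0 genes by edgeR). It was also lost with a block for the line (0 genes), but the same 10 libraries without the block gave 0 as well. It was 3 genes without ESC Host 4, DESeq2 called 6, and 458 genes had an unadjusted p under 0.05. No list member was called, although adjusted over the list alone 2 naive genes and 1 BCL-2 family gene had positive differences. Camera called the naive (median 0.54, adjusted p 7.58e-05), late germ cell (0.56, adjusted p 0.00556) and glycolysis lists (0.18, adjusted p 0.0224) higher, with adjusted p = 0.129, adjusted p = 0.654 and adjusted p = 0.745 with an estimated correlation. It called two-cell-like (-0.80, adjusted p 0.000685) and neuroectoderm (-0.28, adjusted p 0.0103) lower, with adjusted p = 0.745 and adjusted p = 0.129 with an estimated correlation.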

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

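The tests of Rn45s set for the PGC-ESC BaxKO libraries and for their comparison with ESC Host and the 3 tests of chromosome 2 were chosen only after the results were seen, as were the single-library values listed last. The test of X-linked dosage was written before its value was computed, after Dusp9 and the second principal component had been seen, and the Rn45s test of the DKO comparison after the counts with the Rn45s term had been seen.

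The 5 PGC-ESC BaxKO libraries stood apart along Y-linked expression, with lines 2 and 5 on the Y-expressing side and lines 1, 3 and 4 at 0. All 5 are in the low Rn45s set, which argues against that set as the source. The X-linked minus autosomal shift fell by 0.955 (log2) over the range of the Y-linked score in these 5 libraries, against -0.05 to 0.08 for single autosomes. A candidate explanation is that lines 1, 3 and 4 carry 2 active X chromosomes and lines 2 and 5 are XY. Over all 15 libraries the fitted change over the range of the Y-linked score was -0.41. The other lines at 0 for Y-linked genes had lower X-linked minus autosomal values than lines 1, 3 and 4 (BaxHet 0.26, ESC Host 1 0.05, ESC Host 2 -0.29, ESC Host 3 -0.37, DKO 1 -0.26, DKO 2 -0.32). Loss of the Y or of an X, in all or part of their cells, therefore stays open there.

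The Bax lines stood apart from the lines with the C57Bl6J label, with 2834 genes called against ESC Host and 3858 against PGC-ESC DKO. For the Host comparison, genes were first called between PGC-ESC BaxKO 1 and 2 and ESC Host 3 and 4 of the other Rn45s set. Between PGC-ESC BaxKO 3 to 5 and ESC Host 1 and 2, all of the low set, these genes had a median signed difference of 0.372. Their median absolute fold in the choosing libraries was 1.15 (log2). The genes were selected by their values in those libraries, so the drop to 0.372 does not measure the share of the set. The sign was kept for 87.6% of them, and single pairs ran from 0.11 to 0.52. The lowest pairs, 0.11 and 0.20, were those of PGC-ESC BaxKO 5, the Y-expressing line among them. A difference within the low set argues against the set as the source of the whole pattern in these libraries. The lowest pair is too near 0 to exclude a share of the set, which stays open. For the DKO comparison, set and group coincide, and the same genes had a median signed change of 0.403 in ESC BaxKO against ESC Host with the set as a term, under the 0.848 of the comparison itself but above the 0.343 between the Host lines of either set, so the set's share cannot be told apart from the group's. In 100 drawn splits of the 9 Host and PGC-ESC BaxKO libraries the real count of 2834 was the highest (1 of 100, next 1788). In 56 splits of the PGC-ESC libraries 3858 was the highest (1 of 56, next 2405). Both shares are under 0.05, which argues against chance as the source of either count without excluding it. In the next-highest splits PGC-ESC BaxKO 2 and 5 stood against 1, 3 and 4, the division seen in Y-linked expression. The splits therefore hold structure of the lines themselves. Strain label, Bax genotype, time of derivation and the level of EGFP differ together between these lines and stay open as untested. X-linked dosage differs between them in part. A covariate for X-linked expression lowered both counts but left genes called in each comparison, so its share stays open.

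Of the 18 positioned genes called between PGC-ESC DKO and ESC Host, 8 lie on chromosome 2 (44.4%, against 7.81% of tested genes), a pattern seen in these data and not tested in others. With the zinc finger family counted as 1 call, the concentration of calls on any of the chromosomes had a permutation p of 0.0283. The draws treated genes as independent, but Spata5l1, AA467197 and Slc30a4 were counted as separate calls. They lie close together, between 122630625 and 122702663 on chromosome 2. The test therefore cannot decide whether separate loci were spread evenly. Reads shared between near-identical zinc finger genes cannot account for the 4 calls outside that family (AA467197, Pla2g4e, Slc30a4 and Spata5l1, within 2.54 Mb) but stay open for the zinc finger genes. A segment of another strain in the DKO lines is a candidate explanation. For AA467197, Slc30a4, Gm14305 and Gm14410 the mean over ESC BaxKO and ESC Host was 15.5, 10.2, 9.42 and 17.1 CPM. ESC Host alone had 12.3, 11.8, 7.79 and 14.9 CPM, and PGC-ESC DKO 0.0492, 1.85, 0.0876 and 3.00 CPM. These levels argue against a difference found only in the Host lines for these genes. Pla2g4e went the other way, with 0.215 CPM in ESC Host, 16.8 CPM in ESC BaxKO and 19.05 CPM in PGC-ESC DKO. It was the 1 of the 8 called in the same direction in ESC BaxKO against the same Host libraries. A difference shared by Host and Bax lines stays open, and the Bax lines need not carry the same segment. Ccbe1 lies 166.8 kb from Pmaip1 on chromosome 18, and neither Bax nor Bbc3 nor Pmaip1 lies on chromosome 2. A segment of chromosome 2 would therefore not be linked to these engineered genes. EGFP has no position in the annotation used, so linkage to the reporter could not be checked.

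Other splits of the libraries were counted for the remaining comparisons of at least 3 libraries a side. For PGC-ESC DKO against ESC Host, 6 of 35 splits called 19 genes or more, so chance cannot be excluded for the count, and the highest other split called 1904 (ESC Host 4 with DKO 1 and 2 against the rest), which points to a structure of the samples. TMM factors were 0.844 in ESC Host 4, 0.912 in DKO 1 and 0.869 in DKO 2, and 0.952 to 1.027 in the rest. Whether library composition caused that split was not tested. For the comparison balanced over strain label, 7 of 100 drawn splits called 13 or more (highest other 1656), so chance cannot be excluded there either. For EpiLC DKO against PGC-ESC DKO the real split called 7792 genes and the highest other 0 (1 of 10), and 10 splits are too few for a share under 0.05.

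In 56 checks of single libraries against their group, 7 values stood apart, where chance would give about 1 in 20. ESC Host 4 had an early germ cell score of 5.63 (others 4.94 to 4.96), 533 CPM of Bax (283 to 321), 0.547 CPM of EGFP and a Y-linked mean of 3.84 CPM (0 in the others). ESC Host 3 had a mesendoderm score of 1.46 (1.75 to 1.79). PGC-ESC BaxKO 1 had a BCL-2 family score of 4.02 (3.79 to 3.84), and PGC-ESC BaxKO 5 had 5106 CPM of Rn45s (2044 to 2760.3).

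The EpiLC response differed between DKO and Host lines for Ccbe1 (-4.37). The origin effect differed between Bax and C57Bl6J lines for EGFP (-16.34), AA467197 (7.82), Gm14295 (9.61), Ccbe1 (-4.17), Pla2g4e (-6.58), Spic (4.26), Gm14305 (6.21), Slc30a4 (2.94), Gm14410 (2.38), Zfp277 (1.03), Traip (-1.40), Serpina3m (4.91) and Tes (-1.15).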

How the results depend on the processing

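The settings with an Rn45s term, either Rn45s set alone, the X-linked covariate, list scores permuted within strain label or Rn45s set, 15 or 10 libraries without covariate or block, or no libraries of host line 4 were chosen only after the results were seen. Of 219 pairs of a comparison and another setting, 160.0 kept the count of called genes within 1.5 times, and the EpiLC conversions of Host and DKO lines did so in all settings tried. Of 7742 pairs of a called named gene and a setting, 6693 stayed called in the same direction, 1048 were no longer called and 1 turned (Prdm14 in PGC-ESC BaxKO against PGC-ESC DKO, -0.0376 with the X-linked covariate, from 0.78). Where a count moved, the cause was not tested.

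For PGC-ESC BaxKO against ESC BaxKO (6 genes), RLE scaling, the compared groups alone, the Y-linked covariate, that covariate with the Rn45s term, and the 15 ESC and PGC-ESC libraries with or without the X-linked covariate each left 0 called by edgeR, against 1637 at an unadjusted p under 0.05. The Rn45s term and the low set each left 2, no filter gave 10 and DESeq2 70. With DESeq2, counts were 77 for PGC-ESC DKO against ESC Host (19 by edgeR), 58 for the balanced comparison (13), 1416 for ESC BaxKO against ESC Host (821), 33 for EpiLC DKO against EpiLC Host (7), 6 for the difference in EpiLC response (1) and 52 for the difference in origin effect (13). With the compared groups alone they were 9 for PGC-ESC DKO against ESC Host, 1024 for PGC-ESC BaxKO against ESC Host (2834), 136 for ESC BaxKO against ESC Host and 0 for the difference in EpiLC response. The Rn45s term gave 1108 for PGC-ESC BaxKO against ESC Host, 204 for PGC-ESC BaxKO against PGC-ESC DKO (3858) and 7 for the difference in origin effect. Together with the Y-linked covariate it gave 1328, 393 for ESC BaxKO against ESC Host, 272 for PGC-ESC BaxKO against PGC-ESC DKO and 12 for EpiLC DKO against EpiLC Host. The Y-linked covariate alone gave 314 for ESC BaxKO against ESC Host and 12 for EpiLC DKO against EpiLC Host. The low set alone gave 361 for PGC-ESC BaxKO and 33 for ESC BaxKO against ESC Host, and the high set 0 for the difference in EpiLC response. Without host line 4 these were 1676 and 485. In the 15 ESC and PGC-ESC libraries, the X-linked covariate gave 981 for PGC-ESC BaxKO against ESC Host and 973 against PGC-ESC DKO, where these libraries gave 1917 and 2826 without it. For ESC BaxKO against ESC Host they gave 399 without it and 925 with it.

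Leaving out single libraries gave 0 to 12 genes for PGC-ESC BaxKO against ESC BaxKO, 14 to 44 for PGC-ESC DKO against ESC Host, 6 to 23 for the balanced comparison, and 1768 to 3455 for PGC-ESC BaxKO against ESC Host. The ranges were 182 to 1015 for ESC BaxKO against ESC Host, 1552 to 4198 for PGC-ESC BaxKO against PGC-ESC DKO, 5 to 11 for EpiLC DKO against EpiLC Host and 0 to 3 for the difference in EpiLC response.

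EpiLC and parent libraries with the same number are from the same line. Their residuals correlated at 0.232 and 0.236 for the Host and 0.226 to 0.325 for the DKO lines over genes. Pairs of EpiLC and parent libraries with different numbers ran from -0.284 to 0.0638. With 2 EpiLC Host libraries, the values against a parent library have equal size and opposite sign. Libraries of unrelated groups reached 0.472 (PGC-ESC BaxKO 1 with ESC Host 1), so these correlations alone cannot show a shared line. In the 10 libraries of 5 lines, edgeR called 0 genes for the difference in EpiLC response with and without a block for the line. The Host and DKO conversions had 6969 and 8092 genes with it, and 6917 and 8115 without it. In the groups that share only a number, the replicate block gave 406 genes for ESC BaxKO against ESC Host (821 without it). The blocks changed no other count by over 1.5 times.

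Of 44 camera calls of lists at the preset correlation, 6 stood with an estimated correlation, the directional fry test called 29 and its mixed test 89. The overlap of the PGC-ESC against ESC calls of Bax and C57Bl6J lines was 1 gene and could not be counted at an adjusted p under 0.01 or with RLE scaling, where the Bax lines had 0 calls.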

Other observations

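Nnt, a mitochondrial transhydrogenase gene that is damaged in the C57Bl6J strain, was read in every group. Its mean was 44.1 ± 9.79 CPM in ESC Host, 41.2 ± 7.34 CPM in PGC-ESC DKO, 59.5 ± 11.4 CPM in ESC BaxKO and 56.3 CPM in the BaxHet line. In PGC-ESC BaxKO it was at 24.0, 22.0 and 31.6 CPM in lines 1, 3 and 4 and at 59.8 and 67.4 CPM in lines 2 and 5, the same division of lines as for Y-linked genes. In EpiLCs it was at 85.2 ± 2.73 CPM in the Host and 82.7 ± 8.16 CPM in the DKO lines.

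Naive pluripotency scores were 7.67 ± 0.118 in ESC Host, 7.70 ± 0.123 in ESC BaxKO, 7.83 ± 0.111 in PGC-ESC BaxKO and 7.40 ± 0.0964 in PGC-ESC DKO, and 2.696 ± 0.108 and 3.19 ± 0.313 in the Host and DKO EpiLCs. The two-cell-like score was 0.28 ± 0.882 in ESC Host, 1.60 ± 0.717 in PGC-ESC DKO, -1.41 ± 0.181 in ESC BaxKO, -1.23 ± 0.870 in PGC-ESC BaxKO and -1.96 in the BaxHet line.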
